A study of Mus musculus with 34 samples.

How the data were processed

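Whole-cell patch recordings of at most 5 min were followed by collection of the cytosol and nucleus of 34 neurons in 200 to 250 µm slices, per the labels' protocols. The mice were at least 6 weeks old and had received 60 nl of virus per site 2 to 5 weeks before, per the labels' protocols. The deposited table holds raw read counts per gene and cell, and its row names are those that the htseq-count program writes, per the file headers. The submitters' processing notes name STAR 2.7.10a and the build mm39, with no role given. The library kit, its strandedness and the gene annotation release are not given in the sources used here. No molecular identifiers were stated, so intervals from read counts cover counting error only.

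The table has 56949 rows, of which 56941 are genes, 5 hold reads given to no gene and 3 are transgenes. Rows given to no gene and transgene rows were left out of library sizes. Reads that did not align were a median of 32.6% of all reads of a labelled cell, reads ambiguous between genes 7.27%, reads aligned to more than one place 3.46% and reads on no feature 2.25%. The sYFP row had 0 reads. Symbols were matched for 51948 gene rows, and the 4993 rows without one held 0.915% of gene reads. The annotation at hand was GENCODE M21 on another build than mm39, so it was used for exonic lengths and exonic overlap only and no coordinates are given. Of protein-coding genes, 29.6% of those with no exonic overlap had no read, 16.0% of those with up to 50% of their exonic length overlapped and 64.0% of those with more, so unread genes did not rise steadily with overlap. Reads on exonic stretches shared by genes cannot be assigned to one of them, so levels of overlapped genes are uncertain.

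Counts were divided by the gene reads of the cell and scaled to a common total to give CPM, and a gene counted as found at 1 CPM. Gene reads had a median of 2401439 per labelled cell, and the level that 3 reads represent ranged from 0.256 to 19.5 CPM. Weakly expressed genes could therefore be missed in the shallowest cells. A single read also passed 1 CPM there, so the threshold was least strict in those cells. In GN001, the shallowest, all 7701 genes with a read were found at 1 CPM, against a median of 5855 genes per labelled cell. Transgene reads were divided by the same gene reads. The 34 cells came from animals the labels do not name and were treated as 1 sample. Shares are given with exact Clopper-Pearson 95% intervals and single read counts with exact Poisson intervals, and no p-value, standard error or correlation was computed over cells. Title numbers fall into a run of 19 labelled cells under 30 and one of 14 over 58, which the labels do not call batches, and values within each are given for the transgenes, the transmitter sums and some of the genes whose shares differ. No counts were identical between cells.

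Before the data were examined, 48 lists with 316 genes were written, along with the design, the alternatives and the rule for named genes. That rule takes all transgene, core GABAergic and other transmitter genes, the 4 members of each other list found in most cells, the whole calcium-binding list with Nos1, 8 neuropeptides, 8 midbrain and hindbrain factors, 2 members per receptor or channel family and the 20 genes with most spread, leaving out predicted, mitochondrial, ribosomal and haemoglobin genes. A list member found in no cell could also be named. Some genes that the rule takes are not reported here. Genes with most spread were ranked by the squared coefficient of variation over its median in windows of 201 genes ordered by mean, among genes found in 20 to 80% of cells, and the ranking was tested on simulated counts. Names of genes outside the rule, in the closing observations, were chosen after their values were seen.

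The alternatives were a threshold of 1 read or 10 CPM, thinning to 100000 gene reads, a minimum of 100000 gene reads and 2000 genes, inclusion of the left-out cell, each run of title numbers, reads per kilobase, removal of mitochondrial genes, median-of-ratios size factors and no limit on the share of cells. Leaving out cells with 4 or more of 8 microglial markers, or cell GN072, was added after the data were seen. Several tests of explanations in the closing observations replaced earlier versions after those had been run. A first test of carried-over reads used 114 genes with sums within 2-fold of that of the construct and found 0 reads in the left-out cell for 0.877% of them, but these are abundant genes that this cell expresses itself, so that test could not decide. Tests on Y-linked and microglial reads first compared averages of cells sorted by those reads and were recast as counts of cells. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.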

Results

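The RNA content of 34 single neurons was measured, each drawn with its nucleus into a patch pipette from a brainstem slice of an adult mouse that carried Cre under the vesicular GABA transporter gene. A retrograde virus with a Cre-dependent mCherry gene had been placed in the lateral habenula on both sides, so that fluorescent cells of the subventricular tegmental nucleus (SVTg) were those taken to project there. All cells but 1 were described as SVTg and no animal was named. The cells thus formed 1 sample with no comparison group, and no p-values were computed. The submitters set the remaining cell, GN029, aside for a stated lack of transgene expression, which left 33 labelled cells. Reads on genes ranged from 153988 in cell GN001 to 11718426 in cell GN013, with quartiles of 732819 and 4310862. A labelled cell had a median of 5855 genes at 1 CPM or more, CPM being reads scaled to the same total of gene reads in every cell, with quartiles of 4783 and 6738. Percentages below are shares of the 33 labelled cells with at least 1 CPM of a gene, with exact Clopper-Pearson 95% intervals that cover counting error only. For a gene found in 0 of 33 cells the upper bound is 10.6%.

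The first question was whether the cells carried the transgenes used to find them. The cells were taken for their fluorescence and GN029 was set aside, so presence in the others was largely set by that selection. Reads of the mCherry construct were present in all 33 labelled cells, at a median of 1385 CPM and a range from 82.2 in cell GN069 to 7040 in cell GN061. Cre, the recombinase that turns the construct on, was found in 32 of 33 cells (97.0%, 84.2 to 99.9%), at a median of 76.5 and a highest value of 582 CPM in cell GN021. Cell GN062 had 0 Cre reads and 12718 construct reads. Both transgenes were found in all 19 cells with title numbers under 30 and in 13 of the 14 with numbers over 58. The construct row in the table bears a different promoter name from the one in the labels, so it was read as the mCherry construct without regard to promoter.

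**Figure D1:**
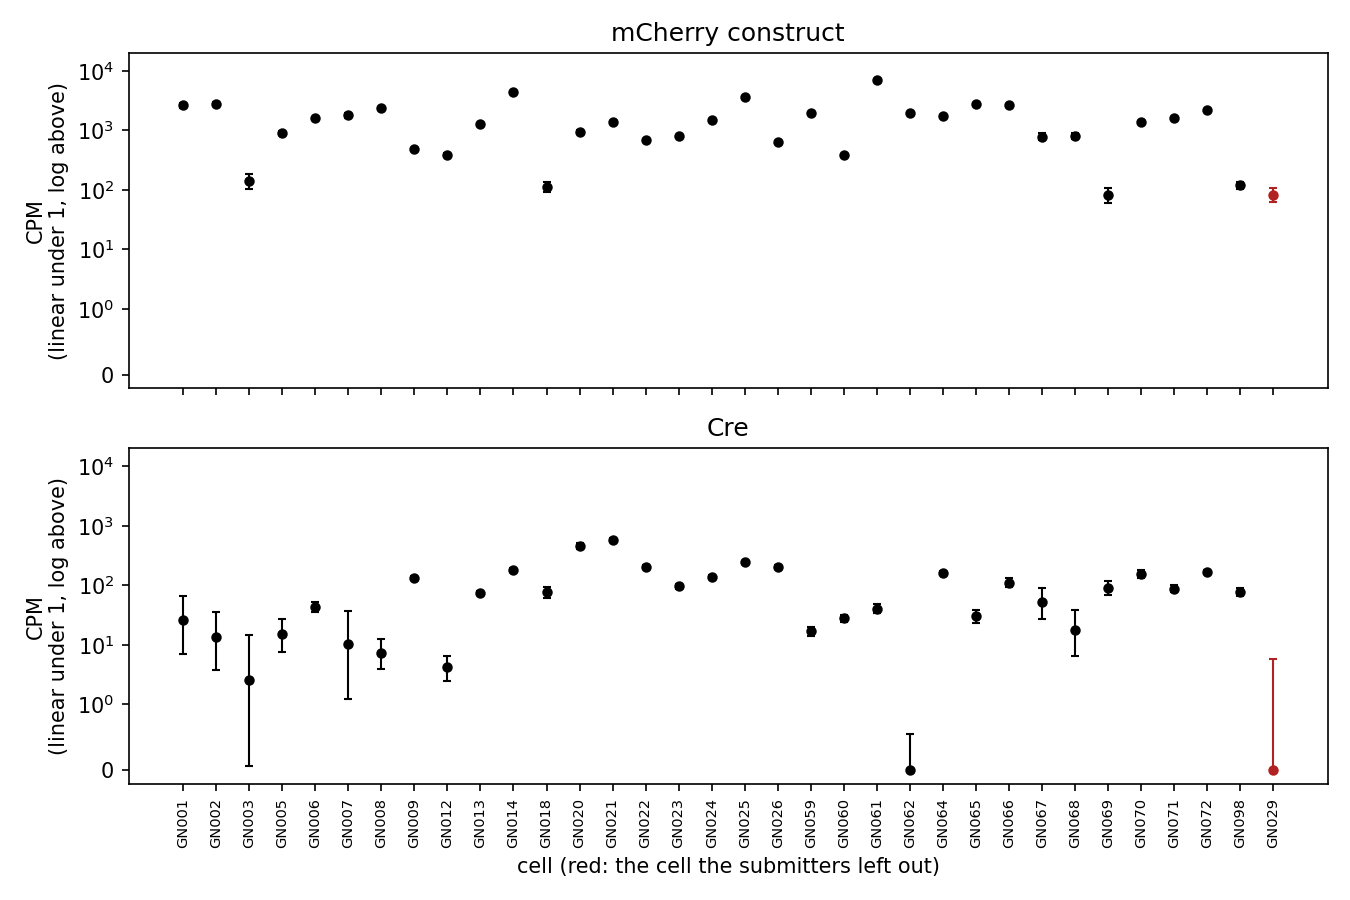
Level in CPM of the mCherry construct (top) and of Cre (bottom) in each cell, with exact Poisson 95% intervals, on an axis that is linear under 1 and logarithmic above. The labelled cells (black) span 82.2 to 7040 for the construct, cell GN062 lies at 0 for Cre, and the left-out cell (red) lies at 82.2 for the construct and 0 for Cre.

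The labelled cells carried GABAergic transcripts. They were picked through Cre driven by the vesicular GABA transporter gene, so this result was favoured by the selection. It does not bear on SVTg cells without the label. Gad2 (ENSMUSG00000026787), which makes GABA from glutamate, was found in 33 of 33 cells (100%, 89.4 to 100%) at a median of 1142 CPM. Gad1 (ENSMUSG00000070880), the other enzyme for this step, was found in 32 cells (97.0%, 84.2 to 99.9%) at a median of 956 CPM. Slc32a1 (ENSMUSG00000037771), the vesicular GABA transporter whose gene drives Cre here, was found in 29 cells (87.9%, 71.8 to 96.6%) at a median of 51.7 CPM. In the reference annotation 24.9% of the Slc32a1 exonic length lies under another gene, so its level is uncertain. All 3 genes were found together in 28 cells (84.8%, 68.1 to 94.9%), and each of the 33 cells had at least 1 of them at 10 CPM. Of the genes that handle GABA after release, the catabolic enzyme Abat was found in 29 cells and the transporter Slc6a11 in 9.

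Transcripts of other transmitter systems were found in fewer cells than Gad1, Gad2 and Slc32a1. A glutamatergic vesicular transporter was found in 15 of 33 cells (45.5%, 28.1 to 63.6%), namely Slc17a6 in 11, Slc17a7 in 6 and Slc17a8 in 4. This share depended on the threshold, at 75.8% with 1 read and 27.3% with 10 CPM. Slc6a5, the glycine transporter of glycinergic terminals, was found in 6 cells, and the histamine enzyme Hdc in 4. Among cholinergic genes Slc5a7 was found in 6 cells, Chat in 4 and Slc18a3 in none. Among serotonergic genes Tph2 was found in 3 cells, and Slc6a4 and Fev in 1 each. Among catecholaminergic genes Slc18a2 was found in 6 cells, Dbh in 4, Th and Slc6a2 in 3 each and Slc6a3 in none. Genes of tissues outside the brain, which bear on misassigned reads and not on RNA of neighbouring cells, gave 3 detections in 396 gene and cell pairs (0.758%). Genes of neighbouring cell types gave more, at 27.7% of pairs for the oligodendrocyte list and 29.5% for the microglial list, so low shares of other transmitter genes were not read as expression by the neurons.

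Within each cell, the summed CPM of the core GABAergic genes was set against that of each other transmitter list. The GABAergic sum was higher than every other list in 33 of 33 cells (100%, 89.4 to 100%), in all 19 cells numbered under 30 and all 14 numbered over 58. Its median was 2312 CPM, with quartiles of 1396 and 3124, against a glutamatergic median of 0.825 CPM and medians of 0 for the glycinergic, cholinergic, serotonergic, catecholaminergic and histaminergic sums. The smallest ratio, 1.81, was in cell GN020, with 761 CPM of GABAergic and 421 CPM of glutamatergic transcripts. That cell had Slc17a6 beside Slc32a1 and Gad2, and no Gad1. A glutamatergic transporter reached 10 CPM in 9 cells, and all 9 had at least 2 core GABAergic genes at 10 CPM. Gad1 and Gad2 together exceeded Slc32a1 in 32 of the 33 cells, GN020 being the exception. Against the vesicular GABA transporter Slc32a1 alone, a glutamatergic vesicular transporter was higher in 7 of 33 cells (21.2%, 8.98 to 38.9%), among them GN062 with 134.7 CPM of Slc17a8 against 25.4 CPM and GN071 with 70.8 CPM of Slc17a6 against 39.98 CPM. In all 7 of these cells Gad1 or Gad2 was higher than the glutamatergic transporter. Since these enzymes also exceeded Slc32a1 in nearly all cells, that comparison could hardly come out otherwise and decides nothing. The GABAergic sums likewise hold both enzymes, whereas the glutamatergic list holds transporters only.

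**Figure D2:**
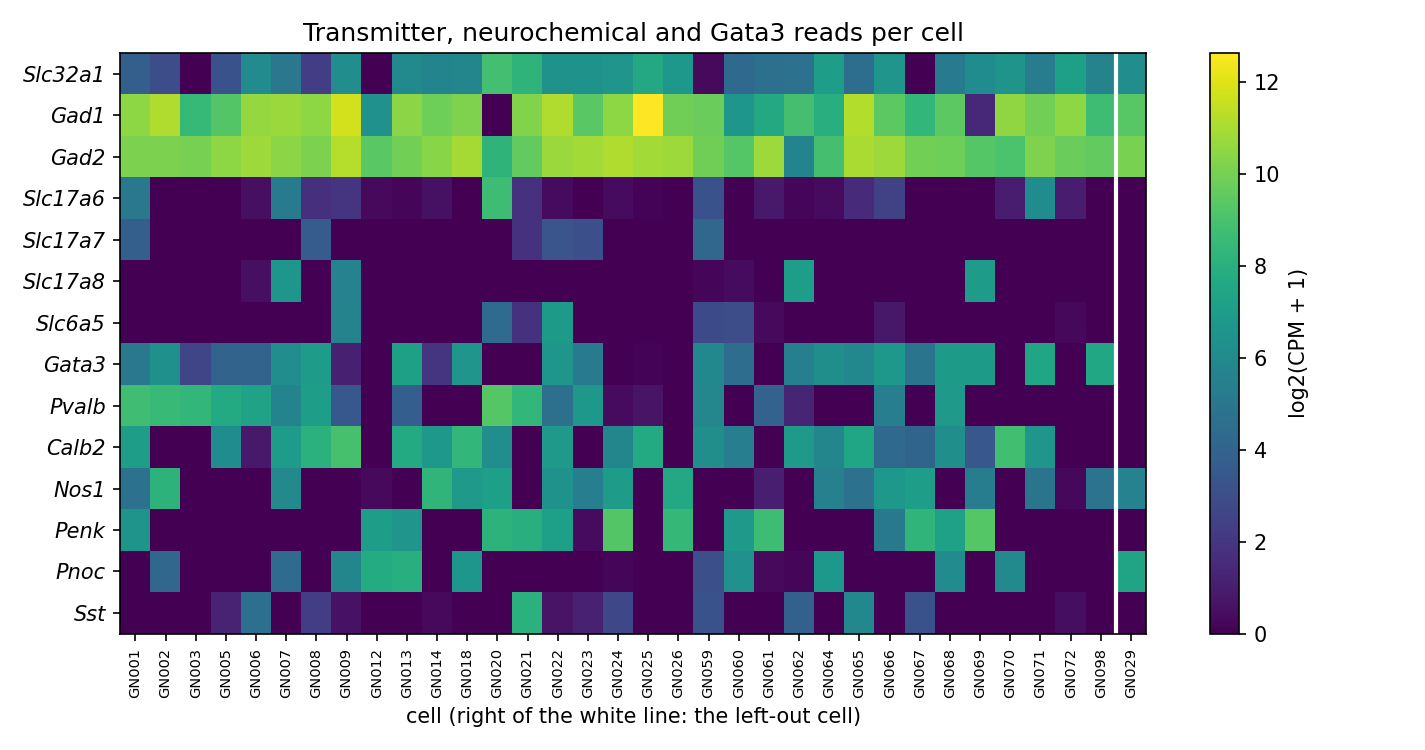
Level of transmitter genes, neurochemical genes and Gata3 (rows) in each cell (columns), as log2(CPM + 1) in colour, with the left-out cell right of the white line. Gad2 is found in all 33 labelled cells, whereas Slc17a6 is found in 11 and Calb2 in 23.

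The neurochemical genes divided the cells in overlapping ways. The calcium-binding protein gene Calb2 was found in 23 cells (69.7%, 51.3 to 84.4%), Pvalb in 18 (54.5%, 36.4 to 71.9%) and Calb1 in 4. The nitric oxide synthase Nos1 was found in 18 cells. Of 26 neuropeptide genes, none was found in at least 50% of cells. Penk led with 14 cells (42.4%, 25.5 to 60.8%), at a median of 194 CPM in the cells that had it, followed by Pnoc with 11, Sst with 10 and Nmb with 9, while Pomc, Tac1, Oxt and Calca were found in 4 each. At 10 CPM, Penk kept 14 cells and Sst 4. Pvalb was found in 13 of the 19 cells numbered under 30 and 5 of the 14 numbered over 58, whereas Calb2 was found in 12 and 11. This difference was not tested.

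Joint detection was counted for the 21 pairs of the 7 neurochemical genes found in 20 to 80% of cells. Pvalb and Calb2 were found together in 12 cells, with 12.5 expected from their shares. Penk and Nmb were found together in 7 cells, with 3.82 expected, the largest excess. Sst and Pnoc were found together in 1 cell, with 3.33 expected. No test was made, and 26 of the 33 cells had at least 2 of Pvalb, Calb2, Nos1 and Penk.

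Some transcription factors of the midbrain and hindbrain were found in many cells. Gata3 (ENSMUSG00000015619), a factor linked to GABAergic neurons of the midbrain and rostral hindbrain, was found in 24 cells (72.7%, 54.5 to 86.7%). These were 13 of the cells numbered under 30 and 11 of those over 58. Its cofactor gene Zfpm2 was found in 17 cells, En1 in 11, Tal1 and Lhx5 in 9 each, Lhx1 and Pax2 in 3 each and En2 in 2. At least 1 of the 16 factors was found in 29 cells (87.9%, 71.8 to 96.6%), whereas Tal2, Pax8 and Nkx6-1 were found in none. The list gave 16.1% of gene and cell pairs, with no interval because pairs share genes and cells. The 9 forebrain factors, Dlx1, Dlx2, Dlx5 and Lhx8 among them, were found in none of the 33 cells, and 7 of them had 0 reads, as did some genes that most cells express. Of 7 Hox genes, which mark the hindbrain behind its first segment, Hoxc4 was found in 1 cell and the other members in none, but overlap with other genes covers 62.8% of the exonic length of Hoxd3 and 52.9% of that of Hoxb3, so their zeros are uncertain.

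Receptors and channels were surveyed to describe which of their transcripts were found with the cells. RNA of neighbouring cells was not excluded, so low shares of these genes were likewise not read as expression by the neurons. Of 152 genes in 24 families, 52 were found in at least 50% of the cells and 20 in none. Ionotropic receptor families differed in how often their members were found, from 90.2% of gene and cell pairs for AMPA and 70.9% for kainate receptors to 37.1% for glycine, 32.8% for GluN2 and GluN3 and 22.2% for nicotinic receptors. The GABA-A families lay between AMPA and glycine receptors, with the beta family above the kainate family. Among the members found most often in each family, Gabrb1, Glrb, Gria1 and Gria4 were found in 31 cells each (93.9%, 79.8 to 99.3%), Grik2 in 32, Grik3 in 28, Gabrg3 in 26, Gabra2 in 25, Grin2b in 23, Grin3a in 20 and Glra1 in 12. Among nicotinic subunits Chrna4 was found in 18 cells and Chrna3 in 14. Among metabotropic receptors, the GABA-B subunit Gabbr1 was found in 32 cells, Grm7 in 31, the nociceptin receptor Oprl1 in 28 (84.8%, 68.1 to 94.9%), Adcyap1r1 and Chrm3 in 25 each, Htr2c and Grm8 in 24 each, Gabbr2 in 22 and Cnr1 in 20. Some of these shares rested on low levels. At 10 CPM, Grm8 kept 9 cells, Grik3 17 and Glra1 5, whereas Gabbr1 kept 32, Grm7 28 and Htr2c 18. Detection was lower for the kappa opioid receptor Oprk1 (16 cells), Adra1a (15), Htr7 (13), Adra2a (11), Drd1 and Tacr3 (10 each), Chrm2 (6), Drd4 (4) and Cnr2 (1). Several shares differed between the runs of title numbers, which was not tested. Cnr1 was found in 8 of the 19 cells numbered under 30 and 12 of the 14 over 58, Gabrg3 in 12 and 14, and Glra1 in 10 and 2, whereas Htr2c was found in 12 and 12.

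Voltage-gated and inward rectifier channels were also described. The sodium channel Scn8a was found in 31 cells and Scn2a in 29. The calcium channel genes Cacna1e and Cacna1c were found in 27 and 25 cells. The potassium channels Kcnc1 and Kcna2 were found in 25 cells each, Kcnc4 in 23, Kcnj9 in 18, and Kcna6, Kcnq3 and Kcnj3 in 14 each. The hyperpolarisation-activated channel Hcn2 was found in 21 cells, and in 14 at 10 CPM. Within families, Glrb was the highest glycine receptor gene in 31 of 32 cells with the family (96.9%), Grik2 the highest kainate receptor gene in 28 of 33 (84.8%) and Grm7 the highest metabotropic glutamate receptor gene in 26 of 33 (78.8%). The gene that led most cells was the same by reads per kilobase in 15 of the 24 families, tied with another in 2 (GABA-A gamma to theta and adrenergic receptors), and differed in 7, namely the GABA-A alpha and beta, AMPA, NMDA, nicotinic, HCN and calcium channel families.

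**Figure D3:**
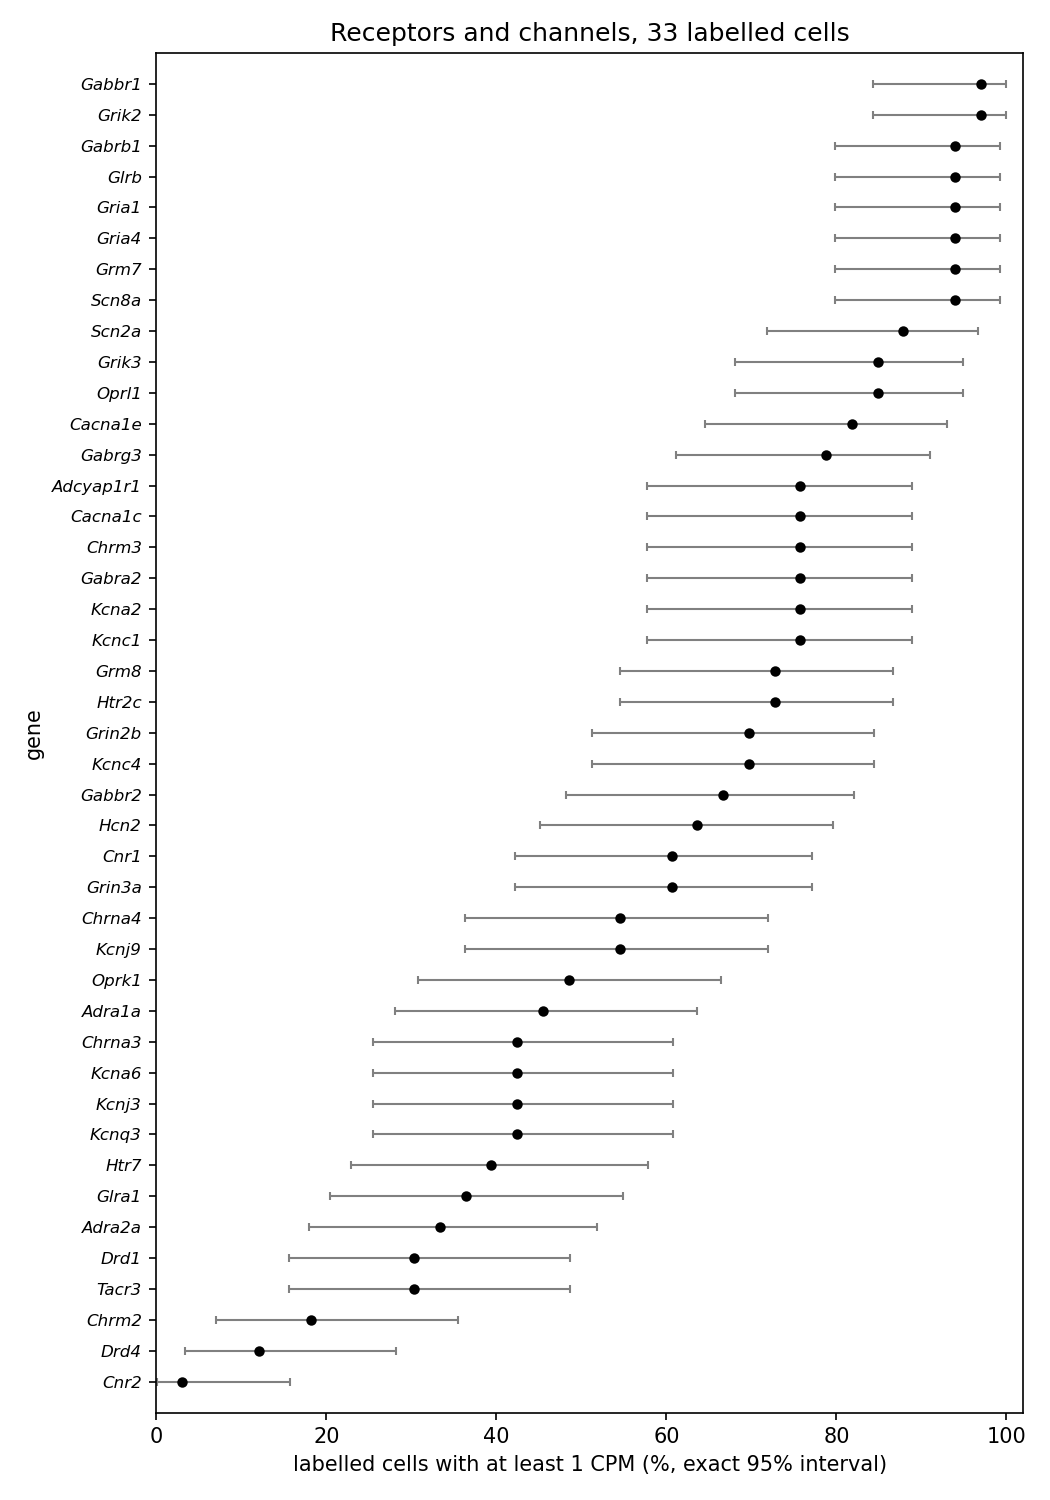
Share of the 33 labelled cells with at least 1 CPM of each receptor or channel gene named in the text (points, in percent) with exact 95% intervals (bars). Gabbr1 and Grik2 lie at 97.0%, Oprl1 at 84.8% and Drd1 at 30.3%.

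Every cell carried neuronal transcripts, and many carried some from other cell types. Snap25, Syt1 and Eno2 were found in 33 of 33 cells and Map2 in 32. At least 50% of the genes of a non-neuronal list were found in 11 cells (33.3%, 17.96 to 51.8%), which was 7 cells for microglia, 5 for oligodendrocytes, 2 for astrocytes, 1 for ependymal cells and 0 for oligodendrocyte precursors, endothelial and mural cells. The shallowest cell, GN001, where a single read passes 1 CPM, was the ependymal one and had the most astrocytic genes. Of the 11 cells, a single read also passed in GN002, GN003, GN020, GN021, GN067 and GN068, but not in GN022, GN023, GN070 and GN071. The share of 33.3% therefore came largely from cells where the threshold was least strict. Mbp, which encodes a myelin protein, was found in 28 cells. Of the microglial genes C1qb was found in 15 cells, C1qa in 11 and C1qc in 8. Of the astrocytic genes Slc1a2 was found in 16 cells, Ntsr2 in 11, Slc1a3 in 8 and Gfap in 7. Among cells numbered under 30 and over 58, Slc1a2 was found in 12 and 4 and C1qc in 7 and 1, but Ntsr2 was found in 4 and 7, Slc1a3 in 3 and 5 and C1qb in 9 and 6, so the members of these lists did not split alike. Shares of glial genes below 100% in these neurons were not read as expression by the neurons.

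Spread over cells beyond what the mean predicts was ranked for 7380 genes. The chemokine Ccl4 ranked highest, with a mean of 351 CPM and 55.9% of its sum in cell GN023. Plek, Cd83 and C5ar1, also known from immune cells, were among the 20 highest genes, with their highest values in cells GN023, GN023 and GN002. These cells also had the highest sums of the microglial list, 3141 CPM in GN023 and 1736 CPM in GN002. Cd83 was not confined to them, being found in 21 of 33 cells at a median of 174 CPM. Of these 20 genes, 15 had their highest value in cell GN072, Fbxl12os, Mcm4 and Clcc1 among them, and only 5 were kept without that cell. GN072 had the fewest genes at 1 CPM, 2299 against a median of 5855, and the highest share of ambiguous reads among reads on genes, 14.4%. In simulated data ranked without the limit on the share of cells, over 13787 and 13783 genes, 200 genes raised in 8 of 33 cells were placed among the 200 highest in 11.5% of cases at 4-fold and 43% at 16-fold. By random ranking, 2.90 of the 200 genes would be placed there. The simulation does not bear on genes high mainly in 1 cell, such as Fbxl12os with 86.1% of its sum in GN072.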

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

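The tests in this part were chosen after the values were seen. The cell that the submitters set aside, GN029, was described by them as expressing neither Cre nor mCherry, and it entered none of the shares and medians of the report, though its levels are plotted beside those of the labelled cells. It had 0 Cre reads and 53 reads of the mCherry construct in 644845 gene reads, or 82.2 CPM (61.6 to 108, exact Poisson 95% interval), which is above what a count of 0 allows. Reads carried over from the other cells numbered under 30 at the construct's own rate of 0.0506% would leave 0 reads in 0.122% of the 1385 genes with sums of at least 10000, and 29.3% of them had 0 reads, which argues against that source as stated. An earlier test of the same idea gave 0.877% on genes the cell itself expresses and could not decide, and carry-over from a few libraries only was not tested. The level equals that of the lowest labelled cell, GN069, at 82.2 CPM from 51 reads, so a low amount of construct RNA in the cell itself remains a candidate explanation.

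The left-out cell also had a core GABAergic sum of 1825 CPM, between the quartiles of the labelled cells at 1396 and 3124 CPM.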

How the results depend on the processing

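The share of cells with both transgenes was 100% among cells numbered under 30, against 97.0% in all labelled cells. The share with a glutamatergic transporter was 75.8% at 1 read and 27.3% at 10 CPM, against 45.5%, which follows from the threshold. Without the 7 cells with at least 4 microglial markers, an alternative chosen after seeing the data, 15.4% of cells had at least 50% of a non-neuronal list, which follows from how those cells were picked. Without cell GN072, also chosen after seeing the data, 5 of the 20 genes with most spread were kept. The other main results stayed within their interval, or within 1.5 times for counts of genes, under the alternatives run for each. Of 144 shares, 129 stayed within their interval when cells were thinned to 100000 reads and 15 were lower, while 23 were lower at 10 CPM and 11 higher at 1 read. Of 150 values, 11 moved among cells numbered under 30 and 30 among those over 58, and the cause was not tested. The minimum of 100000 reads and 2000 genes removed none of the 33 cells and so tested nothing. Inclusion of the left-out cell moved 0 of 150 values, but 1 cell added to 33 could hardly move a share out of its interval. These intervals are wide and the alternatives reuse the same cells, so staying within them is a weak check. Depth limits the shallowest cell most, where 3 reads stand for 19.5 CPM and a single read passes 1 CPM.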

Other observations

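The tests in this part were chosen after the values were seen, as were the genes named outside the fixed lists. The immediate early gene Fos was found in 26 of 33 cells (78.8%, 61.1 to 91.0%), Junb in 21, Egr1 in 20 and Jun in 13. Fos was found in 18 of the 19 cells numbered under 30 and 8 of the 14 numbered over 58, and Jun in 12 and 1, but Junb was found in 13 and 8 and Egr1 in 11 and 9, so these genes did not split alike, and no difference was tested. Of the stress genes Ddit3, the symbol of 2 gene rows that were summed, was found in 21 cells, Hspa1a in 8, Hspa1b in 6 and Atf3 in 5.

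Several genes that are abundant in neurons or in most cells had almost no reads. Nefl and B2m had 0 reads in the 33 labelled cells and Tuba1a had 2, whereas Nefm was found in 29 cells, Nefh in 28, Tubb3 in 32 and Gapdh in 33. Absence of these rows was not read as absence of the transcripts.

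Reads of the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d reached 10 CPM for at least 1 gene in 17 labelled cells and in none of the other 16. Of those 16 cells, 15 were numbered under 30 and 1 over 58. The 4 cells under 30 that had such a gene were GN022, GN023, GN025 and GN026, while GN024 and every labelled cell from GN001 to GN021 lacked one. The break thus lay inside the run under 30, and a difference between the runs alone does not give this pattern. Low depth does not account for the whole pattern, since 7 of the 16 cells had more gene reads than the median of all labelled cells. Animals of both sexes are a candidate explanation. However, Xist, which would separate them, had 0 reads in all labelled cells, the 16 without a Y-linked gene at 10 CPM included. The sex of the animals therefore cannot be told apart from other differences among the cells.

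At least 4 of 8 microglial markers were found in 7 cells (GN001, GN002, GN003, GN022, GN023, GN067 and GN070), against a mean of 4.16 and a highest value of 10 over 10000 shuffles of each marker over cells, so markers picked up independently of each other were not excluded by that count. Of the 7 cells with the highest sums of Ctss, Tyrobp, Fcer1g, Laptm5 and Cd68, 6 were among these cells, with 1.48 expected. RNA of microglia taken up with the cell is a candidate explanation. Of the 7 cells, 4 had Cx3cr1 and 1 had Tmem119, both on the list that picked the cells, while P2ry12 had 0 reads in all labelled cells. With P2ry12 required, as the test first stood, it was undecided, and it goes with the explanation only since that requirement was dropped. Both explanations weighed here are technical, pick-up of RNA from outside the neuron, and no biological one was tested.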
